A study of Homo sapiens with 4 samples.

How the data were processed

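The samples were 4 cultures of sorted human naive CD4+ T cells, 1 control and 1 high-salt culture from each of 2 donors, harvested on day 7. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by the 3' in vitro transcription method, and each culture was hybridised to 1 Affymetrix array. The values deposited by the authors are linear intensity signals, 1 per probe set, made with Affymetrix Expression Console and MAS5 per the submitters' processing notes. Software versions, the chip description file and the genome build are not given in the sources used here. The values showed that each array had been scaled to a common level, since the mean after trimming 2% from each end was 500.1 on all 4 arrays. MAS5 sets each array's level from all of its probe sets, so a change of total RNA per cell, or a shift of most genes in the same direction, would not be visible in the signals.

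Probe sets were named from the platform's annotation table, in which 41091 of the 54675 probe sets had 1 gene symbol, 1801 had several and 11721 had none. The symbols of 41037 were updated through their gene identifiers to a current gene table (assembly GRCh38.p14, used for names alone), and no gene was named from a probe set with several symbols. Control probe sets (62) and probe sets of XIST or Y-linked genes (95) were left out. Probe sets were kept when their mean signal over all 4 arrays was at or above the median of all probe sets (111.6), which left 27259, of which 21822 had 1 symbol and represented 11908 genes. A gene was represented by its brightest kept probe set, and a probe set prone to cross-hybridisation (suffix _x_at) was used where the gene had no other. All columns of the value table were used.

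Signals were analysed as log2(signal + 16), so that fold changes are on this scale and understate the change of dim genes. The planned test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) with group as the only term, and Benjamini-Hochberg adjustment over the kept probe sets at a threshold of 0.05. A second fit, also fixed in advance, added the donor as a replicate block. The pairing comes from the labels, which give the same donor number in both conditions, and the deviations of same-numbered arrays from their group means correlated at 0.738 across kept probe sets. The blocked fit is the one quoted for single genes, because the groups hold the same 2 donors. That preference was settled after the fit without the block had been seen to make no call. Standard errors printed as ± after a log2 change are those of the blocked fit, and levels are means ± SD over 2 arrays. The residual degrees of freedom were 2 without and 1 with the block, the prior degrees of freedom were 3.68 and 61.78, and the median standard errors were 0.65 and 0.37. With 2 arrays per group no exact permutation test could reach the threshold, so all p-values come from limma.

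A count without a test was also planned, of kept probe sets that differed 2-fold or more in the same direction in both donors. Gene lists (37, including 7 of markers of other cell types) were fixed before the data were examined. Those with at least 5 kept genes (32) were tested with limma's camera at a preset inter-gene correlation of 0.01, in the fit without the block, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation no list was called, in either fit. With the donor as a block, the same number of lists was called at the preset correlation, 15. Members of the lists with no probe set of that gene alone were not analysed here. Genes named in the text were chosen by a rule fixed in advance. It takes the 10 largest mean rises and 10 largest mean falls past the planned test, and since none passed, these places were filled by the largest changes among genes changed at least 2-fold in both donors. It adds up to 4 genes with the largest change in the called direction from each called list, and 17 genes chosen in advance. The rule also takes up to 2 genes with the largest change from each list not called, but this part was not carried out. Only HPGDS, of the Th2 list, is named through it, and the counts of named genes below leave HPGDS out. Large changes of other genes in lists not called may therefore go unnamed. STAT4 and BST2 fall outside the rule and were named, after their values were seen, as the members that moved against their list, and GZMB was named, likewise after its values were seen, as a granzyme gene with a change opposite to those of GZMA and GZMK.

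The procedure was tested on simulated data with the signals and pair structure of these arrays. With 200 of 27259 probe sets changed, the blocked fit called 108, of which 33 (30.6%) were false, and it recovered 7% of 2-fold and 68% of 4-fold changes. With 3000 changed it called 1427, of which 48 (3.4%) were false, and it recovered 18.9% and 73.1%. The fit without the block and the blocked fit without the trend called 0 in both simulations. The simulated differences between the donors' salt changes were centred and given random signs. In the real data they leaned one way, since 357 of 372 opposite 2-fold changes were lower in donor 1. The false shares may therefore not hold for these arrays. A simulated list of 20 genes shifted by 0.80 on the log2 scale was called by camera with the preset correlation (adjusted p = 6.59e-08) and missed with an estimated one (adjusted p = 0.702). The test with an estimated correlation thus has little power at this sample size. The simulated probe sets varied independently, so the simulation cannot show whether the preset correlation is safe where genes of a list move together. The estimated correlation of the cell cycle list was 0.227 without the block and 0.677 with it. Adjusted p-values at the preset correlation may be too small for such lists.

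The alternatives tried were pseudocounts of 1 and 64, quantile normalization, centring on the array median, no filter, a filter at the 75th percentile, no variance trend, a threshold of 0.1, 1 probe set per gene, a 1.5-fold limit, the mean over a gene's probe sets, an estimated inter-gene correlation, fry, and leaving out each array. Scaling to the hybridisation controls (by their median or mean log2 signal), exchanging the labels of 1 pair, adding a 2-fold requirement to the blocked test and repeating the blocked fit under the other settings were chosen after seeing the data. Background correction and probe summary were not varied, since the analysis began from summarised signals.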

Results

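Gene expression was measured in human naive CD4+ T cells that had been sorted by flow cytometry and cultured for 7 days under conditions that direct them to become Th17 cells, the helper T cells that secrete interleukin-17. Every culture received plate-bound anti-CD3 (10 µg/ml), soluble anti-CD28 (1 µg/ml), IL-1β (12.5 ng/ml), IL-6, IL-21 and IL-23 (25 ng/ml each) and TGF-β1 (5 ng/ml). The high-salt cultures also received 40 mM additional NaCl, and the control cultures received 0 mM. Cells of 2 donors were used, each in both conditions, which gave 2 arrays per group and 4 arrays in all. Each array held 54675 probe sets, of which 27259 passed the signal filter and were compared. The small number of arrays limits the precision of every value below.

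The comparison of high salt with control asked how added NaCl altered the expression program of cells differentiating towards Th17. With high salt, the Th17 cytokine genes IL17A and IL17F rose 5.64-fold and 3.37-fold, IL2, which encodes the T cell growth factor interleukin-2, rose 13.1-fold, and TNF and IFNG, which encode inflammatory cytokines, rose 3.97-fold and 4.70-fold. SGK1, which encodes a salt-responsive kinase, rose 3.53-fold. In the other direction, CXCR6, a chemokine receptor gene, fell by 3.05 ± 0.38 (SE) on the log2 scale, the granzyme gene GZMA fell by 2.77 ± 0.39 and its relative GZMK fell by 2.94 ± 0.54, and TOX2, which encodes a transcription factor of the TOX family, fell by 4.04 ± 0.43. Each of these genes moved the same way in both donors, which the rule for naming genes required of CXCR6 and TOX2. The 1 other kept probe set of CXCR6 was at −1.79 and did not pass. The words rose and fell are used here for an adjusted p below 0.05 in the limma fit with the donor as a replicate block, which called 1669 probe sets (702 up and 967 down), and 966 genes by the probe set that represents each. The fit fixed in advance, which left the donor out, called 0 probe sets (lowest adjusted p = 1.0). An unadjusted p below 0.05 was reached by 537 (219 higher and 318 lower), fewer than the 1363 that chance alone would give, so no gene named below passed that test.

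The number of probe sets that changed 2-fold or more in the same direction in both donors was 1258, of which 439 were higher and 819 lower with high salt. If the differences of both donors were unrelated, 483.2 would be anticipated from the number that moved 2-fold in each donor. A further 372 moved 2-fold or more in opposite directions, and 357 of these were lower in donor 1 and higher in donor 2. Most of these were dim, since with the 75th percentile filter 15 moved in opposite directions, while 258 were higher and 331 lower in both donors. The split into higher and lower probe sets differed between scalings of the arrays. Quantile normalization gave 546 higher and 605 lower, and centring each array on its median, which sets the balance itself, gave 627 higher and 563 lower, while scaling to the hybridisation controls, chosen after seeing the data, gave 1037 higher and 216 lower by the median control and 592 higher and 325 lower by the mean of their log2 signals. Among probe sets called in the blocked fit, median centring gave 765 up and 540 down, and the hybridisation controls gave 199 up and 72 down by the median and 49 up and 42 down by the mean. Of the 19 named genes that fell, 15 still passed with median centring and 8 with either control scaling, and of the 38 that rose, 38, 18 and 7 still passed. The control scalings shifted all genes nearly alike, and 0 of the 75 named genes changed sign (by the median control, IL17A went from 2.50 to 2.86 and CD27 from −2.29 to −1.93). Across kept probe sets, the high-salt differences of the donors correlated at 0.28, and at 0.53 with the 75th percentile filter. These are correlations across probe sets, which are not independent replicates.

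**Figure D1:**
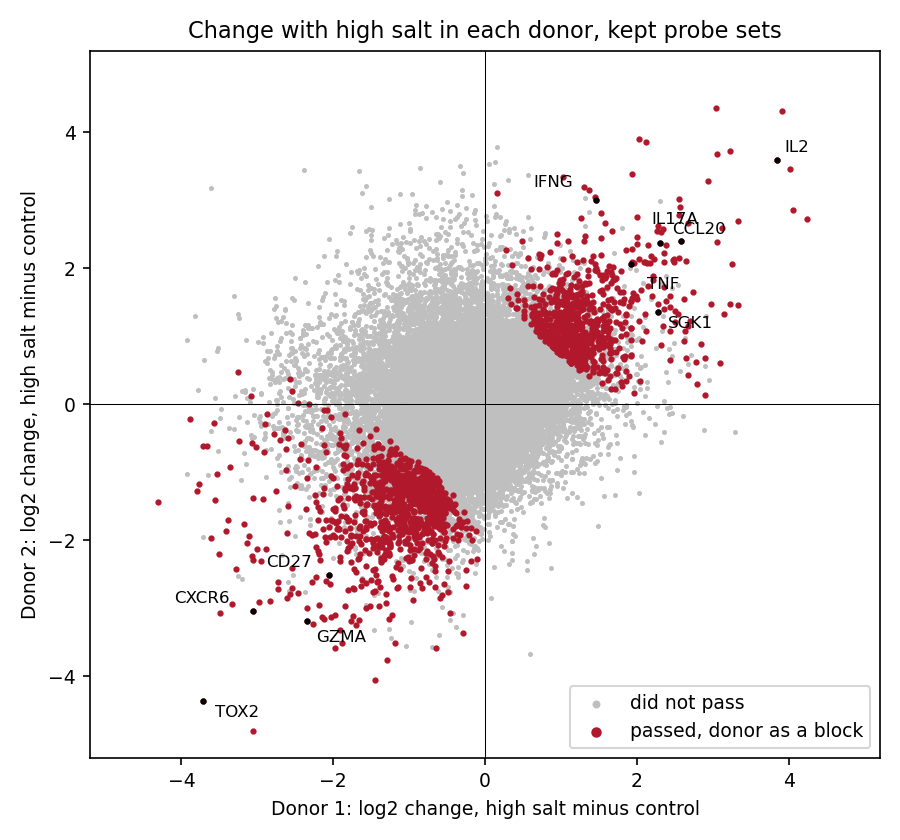
The log2 change with high salt (high salt minus control) of each of the 27259 kept probe sets in donor 1 (x axis) and donor 2 (y axis), with the 1669 probe sets that passed the test with the donor as a block in red and the others in grey. Probe sets in the upper right were higher and those in the lower left lower with high salt in both donors, and black points mark 10 named genes.

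The largest rise among genes changed at least 2-fold in both donors was that of TMEM273, from a signal of 288 ± 149 to 5049 ± 1581 (SD, n = 2), a log2 change of 4.12 ± 0.29 (SE). IL2 followed at the main pseudocount, from 403 ± 232 to 5697 ± 3736 (SD, n = 2), with log2 changes of 3.84 and 3.59 in donors 1 and 2 (adjusted p = 2.35e-15). CDO1, which encodes the cysteine-degrading enzyme cysteine dioxygenase, rose by 3.70 ± 0.43, and EVI5 rose by 3.49 ± 0.30. The genes of the secreted or membrane-bound signalling proteins TNFSF14, CCL4 and OSM rose by 3.46 ± 0.56, 2.99 ± 0.33 and 2.74 ± 0.31. The long non-coding RNA LINC00158 rose by 3.37 ± 0.37, FGD2, which encodes a guanine nucleotide exchange factor, by 2.67 ± 0.29, and S100A2, which encodes a calcium-binding protein, by 2.67 ± 0.28. The 1 other kept probe set of CDO1, TNFSF14 and FGD2 was at 0.39, 0.46 and 0.23 and did not pass, so the size of these rises is uncertain. Mean control signals of CDO1 and TNFSF14, 90.8 ± 91.7 and 58.5 ± 66.0 (SD, n = 2), lay below the filter signal. The sizes and ranks of these rises therefore depend on the pseudocount (with 1, CDO1 was at 4.065, TNFSF14 at 4.073 and IL2 at 3.771). The largest fall at the main pseudocount was that of TOX2, from 1162 ± 111 to 56.4 ± 15.7 (SD, n = 2; adjusted p = 3.86e-10). EPB41L3 fell by 3.28 ± 0.90, and PDE3B, a cyclic nucleotide phosphodiesterase gene, fell by 2.86 ± 0.40. SYTL2, a vesicle trafficking gene, fell by 2.85 ± 0.49, and LGMN, which encodes a lysosomal protease, fell by 2.87 ± 0.90. The log2 changes of TNFRSF19 and MVB12B, −2.89 ± 1.05 and −2.84 ± 1.29, were as large but did not pass (adjusted p = 0.0911 and 0.212), and both genes were dim with high salt, at 17.6 ± 8.68 and 11.9 ± 9.05 (SD, n = 2). Mean high-salt signals of TOX2, GZMK, PDE3B and SYTL2 also lay below the filter signal of 111.6, so the sizes and ranks of these falls depend on the pseudocount (with 1, TOX2 was at −4.37 and EPB41L3 at −4.35). EPB41L3 and LGMN were also dim with high salt, at 22.1 ± 24.2 and 26.4 ± 18.3 (SD, n = 2), and neither passed with a pseudocount of 1, nor LGMN with median centring. The LGMN change was uneven between donors, at −4.31 and −1.43.

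Genes of the Th17 lineage were higher with high salt as a group. Of 16 genes measured above the filter, 7 rose, 0 fell and 9 did not pass (10 rose when adjusted over the list alone), and 13 were higher in both donors. IL17A rose by 2.50 ± 0.28 and IL17F by 1.75 ± 0.28. CCL20, the chemokine ligand of CCR6, rose by 2.34 ± 0.28, CCR6 itself by 1.74 ± 0.30, and IL23R, the receptor subunit for IL-23, by 1.13 ± 0.29. The 1 other kept probe set of IL23R was at 1.03 and did not pass. The median log2 change of the list was 1.01, with 0.82 in donor 1 and 0.98 in donor 2 (camera, adjusted p = 2.91e-07; adjusted p = 0.304 with an estimated correlation). FOXP3, the regulatory T cell transcription factor gene, lay below the signal filter, with a mean signal of 109, and was not tested. Of the 17 genes chosen in advance to be named, 12 were kept, and 4 had no probe set of that gene alone and were not analysed here.

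**Figure D2:**
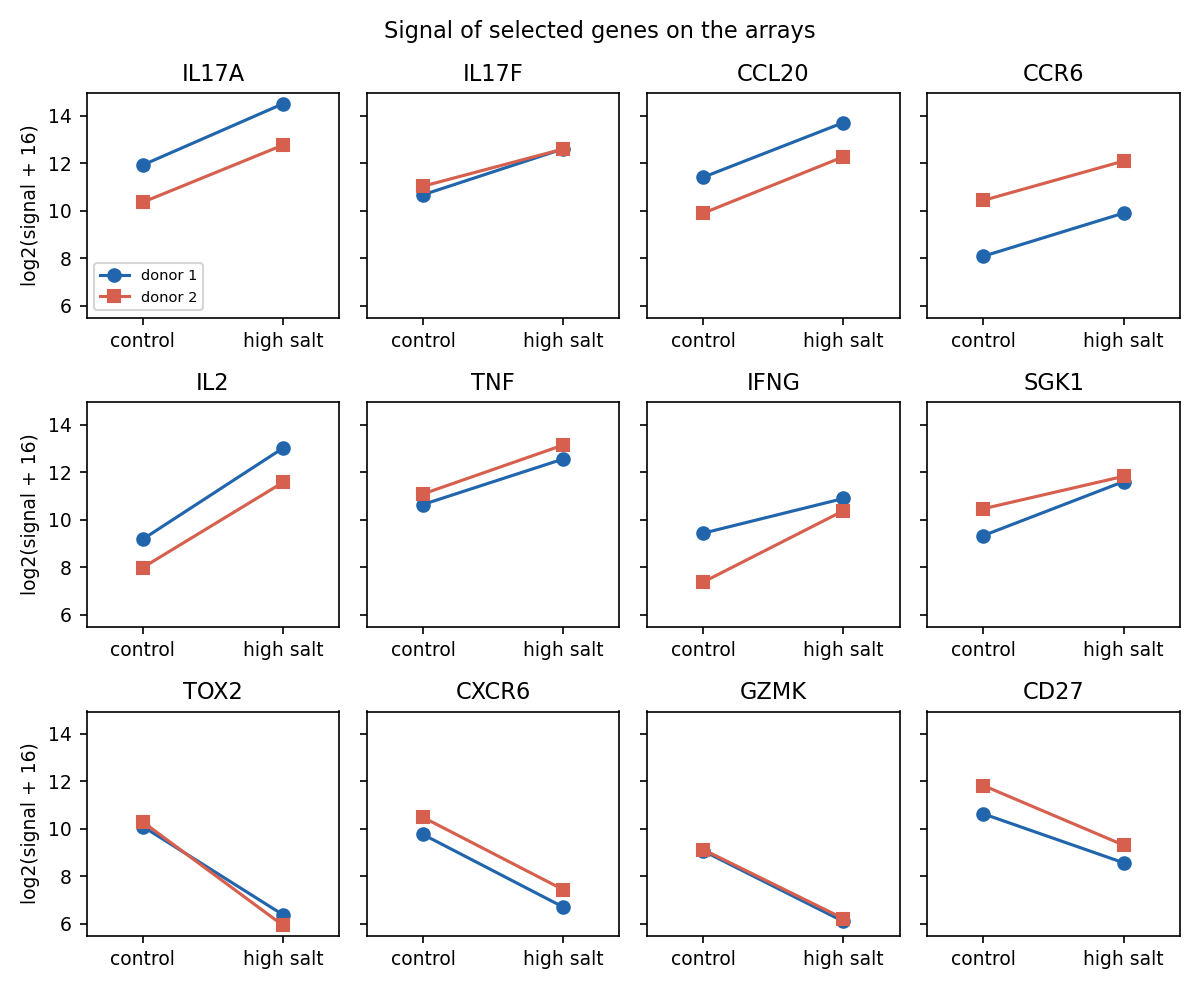
Signal of 12 genes on the 4 arrays, as log2(signal + 16) on the y axis, in control and high-salt cultures (x axis), with a line joining the arrays of each donor. IL17A, IL17F, CCL20, CCR6, IL2, TNF, IFNG and SGK1 were higher, and TOX2, CXCR6, GZMK and CD27 lower, with high salt in both donors.

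Effector genes ascribed to pathogenic Th17 cells were also higher, with 7 of 13 rising, 1 falling and 5 not passing (10 up and 1 down adjusted over the list alone), and a median log2 change of 1.13 (camera, adjusted p = 9.08e-09; adjusted p = 0.304 with an estimated correlation). Besides IL2, CCL20 and CCL4, TNF rose by 1.99 ± 0.28 and the chemokine gene CCL5 by 2.29 ± 0.30. Among Th1 lineage genes, 4 of 11 rose, 1 fell and 6 did not pass (6 up and 1 down adjusted over the list alone), with a median of 0.88 (per-donor medians 0.05 in donor 1 and 0.94 in donor 2; camera, adjusted p = 0.000113; adjusted p = 0.304 with an estimated correlation). IFNG rose by 2.23 ± 0.33, with 1.46 in donor 1 and 3.00 in donor 2, and LTA, which encodes lymphotoxin alpha, rose by 2.08 ± 0.29. STAT4, the signal transducer of IL-12, fell by 1.53 ± 0.31 (adjusted p = 0.000549). TBX21, the gene of the Th1 master regulator T-bet, had a log2 change of 1.11 ± 0.45, from 0.02 in donor 1 and 2.21 in donor 2, and did not pass (adjusted p = 0.148). CCL4, CCL5, IFNG, TBX21, STAT4 and GZMB belonged to both lists. CCL20 and IL23R were counted as rises in the pathogenic list and in the Th17 lineage list. GATA3, which encodes the Th2 transcription factor, fell by 1.25 ± 0.33 (adjusted p = 0.01), whereas HPGDS, also of the Th2 list, rose by 2.31 ± 0.38 (adjusted p = 1.76e-05). The Th2 list as a whole was not called, with 1 of 9 genes rising, 1 falling and 7 not passing (2 up and 1 down adjusted over the list alone; camera, adjusted p = 0.341).

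Genes of the hypertonic stress response were higher, with 3 of 14 rising and 11 not passing (4 up adjusted over the list alone) and a median of 0.47 (camera, adjusted p = 0.000675; adjusted p = 0.304 with an estimated correlation). The members that passed were SGK1, which rose by 1.82 ± 0.29, and the immediate early genes IER3 and CSRNP1, which respond to many stimuli and rose by 1.80 ± 0.30 and 1.11 ± 0.30. SLC38A2, an amino acid transporter gene induced by hypertonicity, had a log2 change of 0.83 ± 0.29 that did not pass (adjusted p = 0.075). NFAT5, the gene of the tonicity-responsive transcription factor, had a log2 change of 0.48 ± 0.28 (adjusted p = 0.389), and its other probe sets ranged from −1.33 to 1.10, so its direction was not settled. Without the high-salt array of donor 1 the list was no longer called (camera, adjusted p = 0.0981). The lists of sodium, potassium and chloride transport genes (17 genes), the p38 MAPK module (19 genes) and the SGK1, FOXO1 and mTOR axis (18 genes) were not called, with camera adjusted p-values of 0.923, 0.693 and 0.923.

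Lists of interferon-stimulated, cytotoxic, naive and memory, and receptor genes were lower with high salt. Interferon-stimulated genes had a median log2 change of −0.85, with 3 of 20 falling, 1 rising and 16 not passing (11 down and 1 up adjusted over the list alone), and 17 were lower in both donors (camera, adjusted p = 1.44e-05; adjusted p = 0.304 with an estimated correlation). EPSTI1 fell by 2.10 ± 0.31 and XAF1 fell by 1.55 ± 0.47, although XAF1 did not pass with median centring or without a filter, whereas IFI44L and OAS3, at −2.48 ± 0.81 and −1.42 ± 0.53, did not pass (adjusted p = 0.0507 and 0.101). The 1 other kept probe set of XAF1 was at −2.34 and did not pass. BST2, which encodes the virus-tethering protein tetherin, was the member that rose, by 1.00 ± 0.29 (adjusted p = 0.0262). Cytotoxic effector genes had a median of −1.02, with 4 of 10 falling and 6 not passing (6 down and 1 up adjusted over the list alone; camera, adjusted p = 0.0032; adjusted p = 0.304 with an estimated correlation). Besides GZMA and GZMK, SRGN, which encodes the granule proteoglycan serglycin, fell by 1.66 ± 0.31 and CST7, a protease inhibitor gene, fell by 1.25 ± 0.32. GZMB, the granzyme B gene, was higher in both donors (1.14 and 0.62), at 0.88 ± 0.31, and did not pass (adjusted p = 0.0774). This list was no longer called without the control array of donor 2 (camera, adjusted p = 0.0807).

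Naive and memory T cell genes had a median log2 change of −0.39, with 3 of 16 falling and 13 not passing (3 down adjusted over the list alone; camera, adjusted p = 0.00639; adjusted p = 0.349 with an estimated correlation). CD27, a costimulatory receptor gene, fell by 2.29 ± 0.30, from 2599 ± 1446 to 494 ± 182 (SD, n = 2). KLF2, the gene of a transcription factor of quiescent T cells, fell by 1.87 ± 0.51, and MAL, the gene of a T cell membrane protein, fell by 1.66 ± 0.31, while S1PR1, the receptor gene for lymph node exit, was at −0.63 ± 0.28 (adjusted p = 0.2). T cell receptor and coreceptor genes had a median of −0.44, with 3 of 18 falling and 15 not passing (5 down adjusted over the list alone; camera, adjusted p = 0.00764; adjusted p = 0.304 with an estimated correlation). CD7 fell by 2.05 ± 0.38, PTPRC, which encodes the phosphatase CD45, fell by 0.99 ± 0.30 and the adaptor gene FYB1 fell by 0.91 ± 0.28, and UBASH3A, at −1.26 ± 0.56, did not pass (adjusted p = 0.192). PTPRC and FYB1 did not pass with median centring. Other probe sets of CD7 and PTPRC were as small as −0.61 and −0.12. In the fit without the donor, the PTPRC change was 0.38 without the high-salt array of donor 2. Leaving out the control or the high-salt array of donor 2 ended the call of the naive and memory list (camera, adjusted p up to 0.113). The receptor list lost its call without the control array of donor 2 or the high-salt array of donor 1 (camera, adjusted p up to 0.27). With scaling to the hybridisation controls by the median, the medians of these lists were −0.03 and −0.09, and by the mean −0.19 and −0.25. The median of all kept probe sets moved alike, from −0.08 to 0.27 and 0.11, so their distance from other genes changed little.

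Genes of proliferation and of chaperones were higher. Cell cycle and DNA replication genes had a median log2 change of 0.60, larger in donor 1 (1.04) than in donor 2 (0.40), and 10 of 35 rose, 0 fell and 25 did not pass (15 up adjusted over the list alone; camera, adjusted p = 8.14e-10; adjusted p = 0.349 with an estimated correlation). CDC45 and MCM2, components of the replicative helicase, rose by 1.78 ± 0.33 and 1.46 ± 0.28, the proliferation marker MKI67 by 1.43 ± 0.28 and the mitotic kinesin gene KIF20A by 1.27 ± 0.29. For MKI67, 1 of 3 other probe sets was near 0, at −0.05. Heat shock and chaperone genes had a median of 0.74, with 5 of 14 rising and 9 not passing (8 up adjusted over the list alone; camera, adjusted p = 1.25e-05; adjusted p = 0.304 with an estimated correlation). HSPA4 rose by 1.38 ± 0.28, HSPH1 by 1.24 ± 0.29, HSP90AB1 by 1.20 ± 0.29 and HSPE1 by 1.16 ± 0.29, although 1 of 3 other HSPA4 probe sets was at −0.42. NF-kB target genes had a median of 0.53, with 3 of 20 rising and 17 not passing (5 up adjusted over the list alone; camera, adjusted p = 0.000184; adjusted p = 0.351 with an estimated correlation). The members that passed were CCL20, TNF and LTA, and CXCL8, at 0.94 ± 0.32, did not (adjusted p = 0.0708). CCL20, TNF and LTA were also counted above as rises in the Th17 lineage, pathogenic Th17 or Th1 lists, so these list results are not independent.

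Metabolic lists were also higher, and few of their members passed. Glycolysis genes had a median log2 change of 0.53, with 2 of 21 rising and 19 not passing (2 up adjusted over the list alone; camera, adjusted p = 1.44e-05; adjusted p = 0.304 with an estimated correlation). HK1, which encodes hexokinase 1, rose by 1.29 ± 0.28, and PKM, the pyruvate kinase gene, by 1.18 ± 0.28, while ALDOA and PFKFB4, at 0.81 ± 0.31 and 0.78 ± 0.31, did not pass (adjusted p = 0.117 and 0.136), and PFKFB4 was at −0.29 in donor 2. The PKM signal differed widely between donors, so that in the fit without the donor its log2 change was −1.05 without the control array of donor 1 and −0.97 without the high-salt array of donor 2. Hypoxia response genes had a median of 0.43, with 0.70 in donor 1 and 0.04 in donor 2, and 3 of 19 rose and 16 did not pass (3 up adjusted over the list alone; camera, adjusted p = 6.11e-05; adjusted p = 0.358 with an estimated correlation). ANKRD37 rose by 2.20 ± 0.30, HILPDA, a lipid droplet gene, by 1.11 ± 0.30 and ADM, which encodes adrenomedullin, by 1.03 ± 0.29, and EGLN3, at 0.98 ± 0.70, did not pass (adjusted p = 0.516). The hypoxia list was not called without the high-salt array of donor 1 (camera, adjusted p = 0.201). Amino acid stress genes downstream of ATF4 (median 0.19) and oxidative phosphorylation genes (median 0.21) were called with camera adjusted p-values of 0.0135 and 0.0192, and both had an adjusted p = 0.426 with an estimated correlation. Of 25 amino acid stress genes 2 rose (3 up and 1 down adjusted over the list alone), ATF3 by 1.38 ± 0.28 and the tRNA synthetase gene WARS1 by 1.12 ± 0.28. The 1 other kept probe set of each, at 0.43 for ATF3 and 0.70 for WARS1, did not pass. GARS1 and SLC7A5, at 0.84 ± 0.29 and 0.63 ± 0.28, did not pass (adjusted p = 0.0724 and 0.201). Of 30 oxidative phosphorylation genes 1 rose, UQCRC1 by 0.92 ± 0.29 (0 adjusted over the list alone), and NDUFV2, CYC1 and NDUFA8, at 0.64, 0.61 and 0.57, did not pass (adjusted p = 0.219, 0.222 and 0.258). Both of these lists lost their call without the control array of donor 2 or the high-salt array of donor 1 (camera, adjusted p up to 0.543), and the oxidative phosphorylation list also with quantile normalization (camera, adjusted p = 0.423), without a filter and with the mean over a gene's probe sets.

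**Figure D3:**
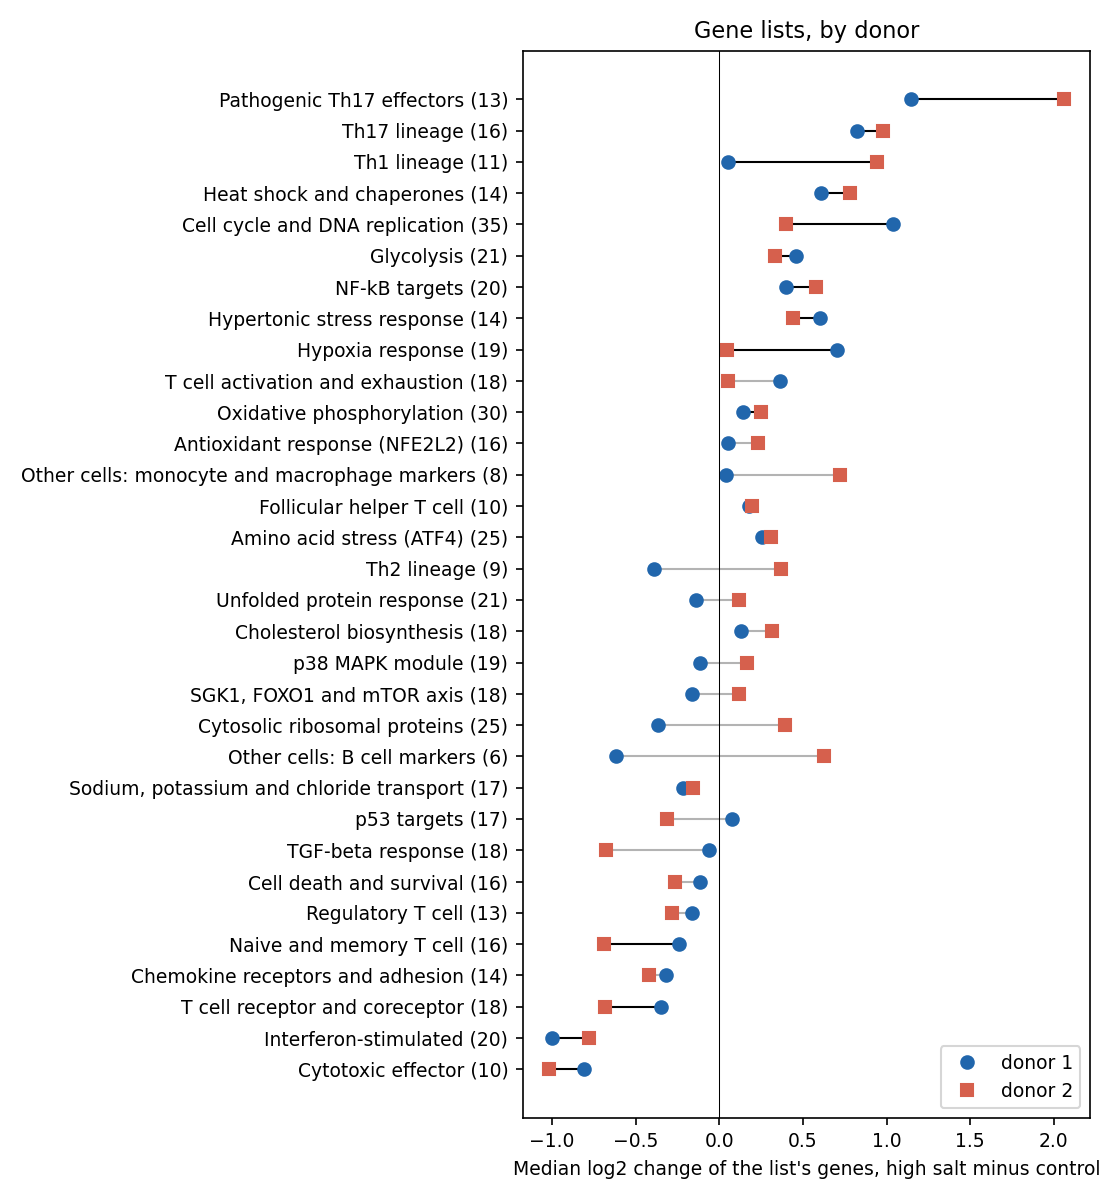
Median log2 change (high salt minus control, x axis) of the genes of each of 32 tested lists in donor 1 (circles) and donor 2 (squares), with the number of genes kept in parentheses. Black lines join the donors for the 15 lists called by camera at the preset correlation and grey lines those for lists not called. The medians of the Th17 lineage list were 0.82 and 0.98 and those of the cytotoxic effector list −0.81 and −1.02.

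The other lists were not called. They were the regulatory T cell list (camera, adjusted p = 0.998), the follicular helper T cell list (0.937), T cell activation and exhaustion (0.167), the unfolded protein response (0.742), cholesterol biosynthesis (0.139), p53 targets (0.544), cell death and survival (0.983), the NFE2L2 antioxidant response (0.501), the TGF-beta response (0.501), chemokine receptors and adhesion (0.0534) and cytosolic ribosomal proteins (0.544). The follicular helper list had a positive median (0.20) and a negative mean (−0.33), and 2 of its 10 genes fell. In the regulatory list the median (−0.36) and the direction of the test differed in sign. The chemokine receptor list, in which 3 of 14 genes fell and CCR6 rose, was called with quantile normalization (camera, adjusted p = 0.0129). At the main settings, the B cell and the monocyte and macrophage lists were the only tested lists of markers of cell types other than CD4+ T cells. Neither was called. Without a filter and with the donor as a block, the gamma-delta and MAIT cell list was called lower (camera, adjusted p = 0.0232). The B cell and the monocyte and macrophage lists had medians of −0.10 and 0.20 (camera, adjusted p = 0.983 and 0.872). The remaining 5 such lists had fewer than 5 genes above the filter and were not tested at these settings. Their medians were 0.19 for 2 NK cell genes, 0.88 for 4 CD8 T cell genes, −0.58 for 2 dendritic cell genes, −0.39 for 4 erythroid and platelet genes and 0.00 for 3 gamma-delta and MAIT cell genes. In the blocked fit, 1 gene each of the monocyte and macrophage, NK cell and CD8 T cell lists rose. In that fit 1 gene each of the CD8 T cell and the gamma-delta and MAIT cell lists fell.

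Measures of array quality differed both between donors and with salt, and they apply to all gene groups above. The ratio of the 5' to the 3' actin probe set was higher with high salt in both donors, at 0.0485 in control and 0.0897 in high salt for donor 1 and 0.250 and 0.309 for donor 2. The same ratio for GAPDH was 0.767 in control and 0.873 in high salt for donor 1, and 0.797 and 0.702 for donor 2. Arrays of a pair correlated at 0.93 and 0.91 across kept probe sets, whereas arrays of the same condition from different donors correlated at 0.78 (control) and 0.77 (high salt). With 2 donors, the blocked fit had 1 residual degree of freedom per probe set and took its error almost wholly from the spread shared across probe sets of like signal. With no trend in the variance model, so that the shared spread no longer follows the signal, it called 0 probe sets (lowest adjusted p = 0.348 in limma). In that fit 3377 had an unadjusted p below 0.05, against 1363 by chance. The calls of the blocked fit thus describe these 2 donors and rest on its error model.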

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

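The alternatives applied to the blocked fit, other than the block itself, were chosen after seeing the data, as was scaling to the hybridisation controls. The count of probe sets called was 0 in the fit without the donor and with every setting fixed in advance except the replicate block, which gave 1669, and it was 0 with each array left out in turn. Exchanging the labels of the second pair in the blocked fit gave 0 (417 at an unadjusted p below 0.05, with 1363 anticipated by chance). The exchange moves the change shared by both donors into the error, so few calls were likely from the outset. It is therefore no null comparison for the 1669 calls. The blocked count was 1883 and 1790 with pseudocounts of 1 and 64, 1734 with quantile normalization (1464 of them among the original 1669), 1305 with median centring, 1493 without a filter and 1417 with the 75th percentile filter. It was 800 when 2-fold in both donors was also required, 271 with scaling to the median hybridisation control and 91 to the mean of their log2 signals, and 0 without the variance trend. The trend lets 1 residual degree of freedom borrow from probe sets of like signal, and the simulation without it also made no call. The count of probe sets changed 2-fold in both donors, 1258, was 797 with a pseudocount of 64, 2249 without a filter, 589 with the 75th percentile filter and 4189 at 1.5-fold, as these settings admit more or fewer dim or small changes. The numbers that moved in opposite directions, against 372 at the main settings, were 101, 2315, 15 and 1577 in the same order. Without a filter, opposite changes thus outnumbered those in the same direction. The same-direction count could not be computed with an array left out, and background and summary were not varied. Scaling to the hybridisation controls turned its split to 1037 higher and 216 lower by the median and 592 higher and 325 lower by the mean. It added nearly the same shift to all genes, 0.69 in donor 1 and 0.01 in donor 2 by the median and 0.63 and −0.245 by the mean. A shift that differs between donors adds to the error of the blocked fit, which is the difference between the donors' changes. The lower blocked counts of 271 and 91 therefore need not mean smaller changes.

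The 15 called lists became 0 with an estimated correlation and 0 with fry, and in the blocked fit 0 and 1 (the cause was not tested), the latter being the Th17 lineage list (fry, adjusted p = 0.0137). Other settings gave 13 to 16, and leaving out an array gave 10 to 18. With camera at the preset correlation and otherwise the main settings, the block changed no list's call. Under other settings it did so for oxidative phosphorylation (each filter alternative), chemokine receptors (pseudocount 64 and no filter) and gamma-delta and MAIT cell markers (no filter). Of 961 values of the 75 named genes under alternatives, 7 reversed, in 6 genes, and 57 passed, all with the block. Since none passes without the block, the side of the threshold says nothing there. Of those 57, between 53 and 57 still passed in the blocked fit with the other pseudocounts, normalizations and no filter, 50 of 50 tested with the 75th percentile filter, 26 and 15 with the control scalings (0 of 75 changed sign, as all genes shifted nearly alike) and 0 without the trend. The reversals came from leaving out an array, which leaves 1 array in a group and removes the pairing, so that the donor difference enters the contrast. The ranges were −1.05 to 3.41 for PKM (also −0.97), −0.028 to 1.58 for PFKFB4, −0.091 to 2.31 for TBX21, −0.36 to 1.32 for NFAT5, −2.37 to 0.38 for PTPRC and −0.17 to 1.43 for SLC7A5. Probe sets near the filter signal of 111.6 lie close to background, where MAS5 signals are least precise.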

Other observations

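The families in this paragraph and the next, and all tests below except those of array preparation, dim probe sets and RNA integrity, were chosen after the data had been seen. Among 16 gene families picked by symbol, metallothionein genes, which encode zinc-binding and copper-binding proteins, were lower with high salt. Of 6 kept genes 5 fell, with a median log2 change of −1.11, and MT1E fell by 1.97 ± 0.28 and MT1H by 1.74 ± 0.28 (SE, donor as a block). Their probe sets share near-identical sequence, so the values of single members are uncertain. The count and the test of this family treat them as separate genes, although they may partly repeat the same measurement. GIMAP genes, which encode lymphocyte GTPases, also fell in 4 of 6 cases, with a median of −1.20, and GIMAP4 fell by 1.52 ± 0.28. Of 346 genes with ZNF symbols, most of which encode zinc finger transcription factors, 41 fell, 2 rose and 303 did not pass, with a median of −0.55, and 215 were lower in both donors. With camera at the preset correlation in the blocked fit, the adjusted p-values over the 16 families were 9.02e-09, 2.38e-06 and 1.02e-06. All 3 had an adjusted p = 0.447 with an estimated correlation.

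The 4 families that follow were among those that were higher. Nucleolar ribosome biogenesis factors had a median of 0.52, and 8 of 45 rose, among them WDR75 by 2.22 ± 0.28. Of 8 CCT chaperonin subunits 3 rose (median 0.75), CCT5 by 1.61 ± 0.29. Of 75 mitochondrial ribosomal protein genes 6 rose (median 0.32) and 53 were higher in both donors, and of 34 proteasome genes 2 rose (median 0.43) and 26 were higher in both donors. The adjusted p-values of these 4 families were 3.36e-07, 3.35e-06, 7.74e-07 and 2.38e-06 at the preset correlation and 0.447 with an estimated correlation. Nuclear pore proteins (22 genes, median 0.31) and cytosolic aminoacyl-tRNA synthetases (15 genes, median 0.42) were also called higher. Their camera adjusted p-values in the blocked fit were 0.0107 and 0.00121 at the preset correlation and 0.447 with an estimated correlation. The 50 translation initiation factors had a median of 0.022, with 19 higher and 19 lower in both donors, and were not called (adjusted p = 0.0926). The KLF, TRIM, RAB, solute carrier, long non-coding RNA and histone families were not called either. The 25 cytosolic ribosomal protein genes had a median of 0.00, with −0.36 in donor 1 and 0.40 in donor 2. With scaling to the median hybridisation control, which moved the median of all kept probe sets from −0.08 to 0.27, the medians of the lower families were −0.74 for metallothioneins, −0.84 for GIMAP genes and −0.20 for ZNF genes.

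No probe set passed without the donor term and 1669 passed with it. Both fits gave the same log2 changes, and the median residual SD was 0.613 without the term and 0.274 with it. The deviations of same-numbered arrays from their group means correlated at 0.738. Differences shared by both arrays of a donor enter the error of the fit without the term and are a candidate explanation for its lack of calls. Part of these differences may come from how the arrays were prepared, because the donor difference was less alike among probe sets of a gene than the salt difference (intraclass correlations 0.147 and 0.472, gap −0.324, 95% bootstrap interval −0.349 to −0.296), and poly-A spike signals had a median of 791 and 492 on the arrays of donor 1 and 4.61 and 19.0 on those of donor 2. Of 971 other probe sets of called genes, 87.7% moved in the called direction, compared with 64.1% for genes not called. This was above the share set in advance for RNA integrity or labelling as the source of the salt calls. A difference in integrity or labelling that acts on a whole transcript would also move its probe sets together, so the test cannot exclude this source. Biological differences between the donors stay open and were not tested separately.

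GZMA and GZMK fell with high salt, whereas CCL4, CCL5 and IFNG, which cytotoxic cells also express, rose. A loss of contaminating CD8 T or NK cells could lower granzymes, although the cells had been sorted as naive CD4+ T cells. The other kept CD8 and NK markers (CD8A, CD8B, NCR3 and GNLY) had a median log2 change of 0.551 in donor 1 and 0.84 in donor 2. They went both ways, with NCR3 at 1.38 and GNLY at −0.99, and were dim, at control signals of 60.2 to 437. Such a loss therefore cannot be told apart from an effect of salt on the CD4+ T cells.

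More probe sets were lower than higher by 2-fold in both donors, without a test (65.1% lower). Quantile normalization brought this share to 52.6%, and the authors' scaling as its source cannot be told apart from a true excess of lower signals. Among probe sets above the 75th percentile of signal the share was 56.2%, just past the limit set in advance against noise of dim probe sets. Its 95% exact interval, 52.1% to 60.2%, treats probe sets as independent and reaches below that limit. Noise of dim probe sets therefore cannot be told apart either. The median change over hybridisation controls was −0.67 in donor 1 and 0.30 in donor 2, and over an older set of them −0.63 and −0.25, while scaling by each array's median control moved donor 2 by only 0.01, so the controls disagree in donor 2. A net loss of transcripts with high salt therefore has no firm basis in these data.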
